A study of Mus musculus with 6 samples.

How the data were processed

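Gene expression was measured in total RNA from whole mouse brain on 6 one-colour oligonucleotide arrays, 1 brain sample per array. The labels give 3 groups of 2 arrays, all from C57/Bl6 mice at 2 months of age. NestinCre control brains carried the Nestin-Cre transgene, which expresses Cre recombinase in neural progenitors and their progeny, and unaltered Pofut1. Flox control brains carried 2 floxed copies of Pofut1 and no Cre. Knockout brains carried both the transgene and 2 floxed copies. Per the labels' protocols, RNA was extracted with Trizol and a silica membrane, and 25 ng was amplified and labelled with biotin by the Ovation system.

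The deposited values are intensities on a linear scale, with 1 value per probe set and array. GCOS and RMA are named in the submitters' processing notes, with no version, role or order. RMA subtracts background, gives all arrays a common distribution and summarises the probes of a set, which compresses differences of dim probe sets and removes any shift shared by most genes. The program that ran it and any filter are not given in the sources used here. The values looked linear, not log2: the lowest lay near 38.1 on each array, and array medians were 7.32 to 7.36 after log2. The test had been planned for log2 values, so log2 of each deposited intensity was taken first.

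The table held 45101 probe sets. The 64 control probe sets were left out, which left 45037 for testing. Of these, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed. Only probe sets with 1 symbol were named. The Entrez identifiers of 34741 matched the mouse RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order only. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed.

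Differences were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 3 groups, and lmFit and eBayes were run without trend over all 6 arrays, so that the groups shared 1 estimate of the spread. The residual degrees of freedom were 3, and 4.94 with the prior. The knockout mean was compared with the average of both control means, which was the main comparison, and with each control alone, and the controls were compared with each other. Benjamini-Hochberg adjustment covered all 45037 probe sets with a threshold of 0.05. A standard error (SE) is that of the limma log2 difference. The labels speak of replicate brains and do not say how the RNA samples relate to animals, so p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision.

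Before the data were examined, the design, the alternatives, 43 gene lists and the rule for named genes were fixed. Lists covered the Notch pathway, neural progenitors, brain cell types, brain regions, immune responses, stress, metabolism and neighbours of Pofut1. They were tested at gene level, with the brightest probe set of each of 18194 genes, by limma's camera with a preset correlation of 0.01. Camera with an estimated correlation and limma's fry were run beside it, and adjustment covered the 43 lists of a comparison. Members were also adjusted over the list alone.

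Pofut1 was always named. For the main comparison, the rule took up to 12 genes in each direction with the largest log2 difference among 1-symbol probe sets past the threshold. Both knockout arrays had to lie beyond all 4 controls, and the brighter side had to exceed the median of all probe sets, 7.34 on the log2 scale. Free places were filled by the smallest unadjusted p under 0.01. The other comparisons took up to 5 genes per direction in the same way, and each list up to 4 members by smallest p in the main comparison. Genes named outside the rule are said to be so.

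The alternatives were a repeated quantile normalization, centring on array medians, filters on dim probe sets, an intensity trend in eBayes with and without robust fitting, fits on the compared groups alone, the replicate number as a block, 1 probe set per gene, control probe sets kept, log2 of the value plus 16, and each array left out in turn. Sex as a covariate and the female arrays alone were added after seeing the data, because Xist and Eif2s3y showed that arrays differed in sex. The female arrays are 1 knockout, 1 NestinCre control and 2 Flox control arrays. Their spread is therefore that of the 2 Flox control arrays only. The limma step was tested on simulated data with the means and spreads of the 45037 probe sets in the knockout versus both controls comparison. It recovered 13.4% of probe sets changed by 0.5 on the log2 scale, 44.8% of those changed by 1 and 80.3% by 2. Among unchanged probe sets, 1 was called. The changed probe sets were drawn only from those above the median brightness, so these shares do not cover dim probe sets. In a simulation of the same comparison over 18194 genes, 1 of 41 lists was shifted by 0.3. It was called by limma's camera with the preset correlation (adjusted p = 1.95e-22) and not with an estimated correlation (adjusted p = 0.0651), and no unshifted list was called by either. Genes were drawn independently in these simulations, so they cannot show how the preset correlation behaves when list members are correlated. In the real data the estimated correlation was 0.33 for antigen presentation genes and 0.70 for glucocorticoid and stress genes.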

Results

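The series asks what loss of Pofut1 does to adult neural progenitor cells. Pofut1 encodes the protein O-fucosyltransferase that places fucose on EGF-like repeats, a modification needed for Notch receptor function. Whole-brain expression was compared between 2 knockout arrays, 2 NestinCre control arrays and 2 Flox control arrays. Array medians ran from 7.32 to 7.36 on the log2 scale. Replicate arrays correlated at 0.993 to 0.995 over all probe sets and arrays of different groups at 0.985 to 0.995. The highest of the 15 pairs was NestinCre control replicate 2 with knockout replicate 1. It stayed the highest without probe sets of genes on X or Y, at 0.99518 against 0.99515 for the 2 NestinCre control arrays. By Xist, transcribed from the inactive X chromosome, and the Y-linked Eif2s3y, NestinCre control replicate 2 and knockout replicate 1 were from males and the other 4 arrays from females.

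Pofut1 itself was lower in knockout brain. Its brightest probe set had a mean intensity of 896 ± 31.0 (SD, n = 2) in NestinCre control, 946 ± 65.7 (SD, n = 2) in Flox control and 653 ± 60.7 (SD, n = 2) in knockout. Knockout stood at 70.8% of the controls, a log2 difference of -0.50 (SE 0.08), and both knockout arrays lay below all 4 controls. Over the 3 Pofut1 probe sets alone the limma adjusted p was 0.00511, and over all probe sets it was 0.211, which did not pass. The other probe sets were dim and differed by -0.32 (SE 0.08) and -0.18 (SE 0.07). Where these probe sets lie relative to the deleted part is not given in the sources used here, so they check the labels only in part.

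Knockout brain was compared with both control groups to find what differs when Pofut1 is deleted in Nestin-expressing cells and their progeny. The genes that fell were Nrarp, a Notch target that feeds back on the pathway, Rgs5, a regulator of G protein signalling found in pericytes, Notch3, the Notch receptor of vascular mural cells, and the RIKEN transcript 2900052N01Rik. Nrarp fell 5.06-fold (log2 difference -2.34, SE 0.12), Rgs5 4.47-fold (-2.16, SE 0.08), 2900052N01Rik 4.33-fold (-2.11, SE 0.07) and Notch3 2.16-fold (-1.11, SE 0.05). The genes that rose were Paip1, a translation regulator that binds poly(A)-binding protein, Fcgr4, an IgG receptor of myeloid cells, and Cxcl10, an interferon-induced chemokine. Paip1 rose 3.56-fold (1.83, SE 0.08), Fcgr4 3.36-fold (1.75, SE 0.08) and Cxcl10 2.47-fold (1.30, SE 0.06). For each of these genes both knockout arrays lay beyond all 4 controls.

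These 7 probe sets were all that passed among 45037, with limma adjusted p between 0.0263 and 0.0457. At an unadjusted p under 0.05 there were 5010, against 2251.8 expected by chance. This excess is not particular to knockout, since the same count between the controls was 4693. It was 2617 for knockout against NestinCre control and 7179 against Flox control. The 3 probe sets of 2900052N01Rik, the 4 of Rgs5 and the 2 each of Nrarp and Notch3 all differed in the same direction, whereas only 2 of the 4 for Paip1 did. Leaving out any 1 array gave 0 or 1 call, and 0 of the 7 were among them. With sex as a covariate or with the female arrays alone, both added after seeing the data, there were 0 calls, with 4622 and 3051 probe sets at an unadjusted p under 0.05. The covariate left Rgs5 at -2.20 (SE 0.06) and Nrarp at -2.34 (SE 0.14), while the residual degrees of freedom went from 3 to 2 and the limma adjusted p of the 7 became 0.146 to 0.161.

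The other genes taken by the rule did not pass over all probe sets. Among those higher in knockout were the ferroxidase ceruloplasmin (Cp, log2 difference 0.74, SE 0.05), the class I histocompatibility gene H2-D1 (0.87, SE 0.05), the lysosomal metal transporter Slc11a1 (0.87, SE 0.06), the leukocyte receptor Cd84 (0.76, SE 0.06) and the lysosomal protease Ctsc (0.59, SE 0.05). AU020206 (0.79), Gm4951 (0.95), the splicing factor Rbm5 (0.59) and the insulin-degrading enzyme Ide (0.55) were also higher. Lower were the sulphate donor synthase Papss2 (-1.49, SE 0.08), the pericyte marker Higd1b (-0.96, SE 0.05), Cyp4f15 (-1.75, SE 0.10), the receptor P2ry14 (-0.91, SE 0.06), Gm11627 (-2.54, SE 0.17), Prex2 (-0.78, SE 0.05), the ectonucleotidase Entpd2 (-1.13, SE 0.08) and monoamine oxidase B (Maob, -0.66, SE 0.05). Limma adjusted p ran from 0.0501 for Papss2 to 0.0890 for Rbm5, Ide and Ctsc.

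**Figure D1:**
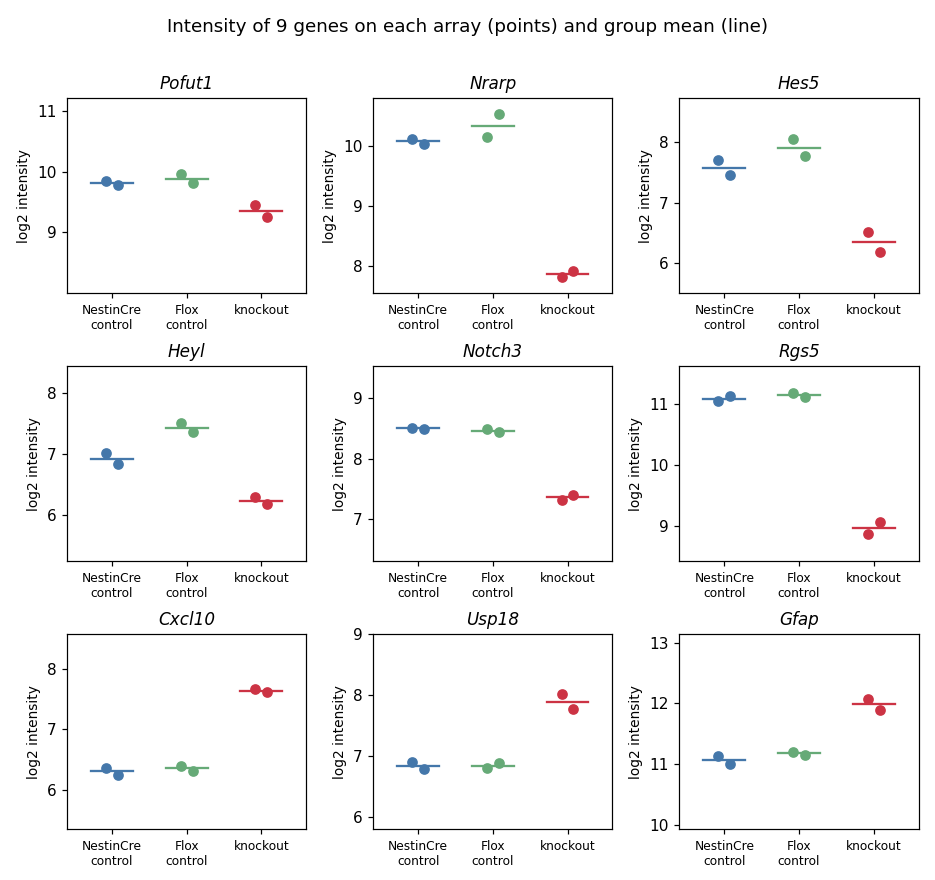
Log2 intensity (vertical axis) of 9 genes on each array, with points for the arrays of NestinCre control, Flox control and knockout and a line at each group mean. Each panel has its own range; both knockout arrays lie below all 4 controls for Pofut1, Nrarp, Hes5, Heyl, Notch3 and Rgs5, and above them for Cxcl10, Usp18 and Gfap.

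Among 17 measured Notch target genes, 4 fell and 1 rose when adjusted over the list alone. Nrarp, Hes5 (-1.38, SE 0.14) and Heyl (-0.94, SE 0.08), both transcriptional repressors, fell with Hes1 (-0.26, SE 0.07). The astrocyte filament gene Gfap rose (0.86, SE 0.07). Over all probe sets only Nrarp passed, and the list as a whole did not pass in limma's camera (adjusted p = 0.0831; 0.530 with an estimated correlation). Of 14 Notch receptors and ligands, Notch3 fell and the other 13 did not pass over the list alone, with Notch4 at -0.36 (SE 0.18), Dlk1 at 0.16 (SE 0.11) and Jag2 at 0.12 (SE 0.09). That list had a limma camera adjusted p of 0.865, as did the 31 measured genes of the pathway's enzymes and transport, none of which passed.

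Genes of pericytes and vascular smooth muscle fell as a group. Of 16 measured, 15 were below 0 with a median of -0.46, and 10 fell when adjusted over the list alone, among them Rgs5, Higd1b, the actin-binding Tpm2 (-0.54, SE 0.06) and the smooth muscle myosin Myh11 (-0.86, SE 0.12). Over all probe sets only Rgs5 passed in this gene-level selection. Limma's camera gave an adjusted p of 2.46e-11 with the preset correlation and 0.183 with an estimated correlation, and fry gave 0.00860. Endothelial genes had a median of 0.03, and none of 18 passed over the list alone (camera adjusted p = 0.0753).

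Interferon-response genes rose as a group. All 19 measured were above 0, with a median of 0.43, and 10 rose when adjusted over the list alone. The smallest p belonged to Usp18, an ISG15 protease (1.05, SE 0.09), Ifit1 (0.73, SE 0.06), the guanylate-binding protein Gbp3 (0.65, SE 0.07) and Ifi27 (0.68, SE 0.09). None passed over all probe sets. Limma's camera gave an adjusted p of 4.42e-19, and 0.152 with an estimated correlation, and fry gave 0.00860. In the same direction were 14 antigen presentation genes (median 0.25, 6 rose over the list alone, limma camera adjusted p = 4.56e-09, or 0.497 with an estimated correlation), with H2-K1 at 0.72 (SE 0.08), Psmb8 at 0.55 (SE 0.06) and Nlrc5 at 0.99 (SE 0.12). Antigen presentation genes also differed between the controls, with a median of -0.24 for NestinCre against Flox control and 12 of 14 below 0. That list did not pass there (limma camera adjusted p = 0.0814). Against Flox control alone the knockout median was 0.17.

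Microglial and macrophage genes also rose. Of 24 measured, 23 were above 0 with a median of 0.17, and 7 rose over the list alone, including Aif1 (0.70, SE 0.06), the leukocyte phosphatase Ptprc (0.70, SE 0.09), Tyrobp (0.48, SE 0.07) and the mannose receptor Mrc1 (0.41, SE 0.08). Limma's camera gave an adjusted p of 4.19e-11, or 0.183 with an estimated correlation. Of 22 cytokines and chemokines 17 were above 0. Over the list alone 4 rose, among them Cxcl10, Cxcl13 (0.49, SE 0.05) and Ccl12 (0.83, SE 0.10), and 2 fell, among them Ccl9 (-0.84, SE 0.12). Their median was 0.13 and the limma camera adjusted p 5.37e-05, or 0.183 with an estimated correlation, and fry gave 7.74e-04. With only the 6 brighter members the direction turned (adjusted p = 0.377). Of 23 reactive astrocyte genes 5 rose over the list alone, with Cxcl10, Gfap, H2-D1 and Psmb8 first. Their median was 0.03, with a limma camera adjusted p of 1.99e-04, or 0.530 with an estimated correlation. Cxcl10 is also on the cytokine list, and H2-D1 and Psmb8 are on the antigen presentation list. Against Flox control alone the reactive astrocyte median was -0.0038, with 11 genes above 0 and 12 below. NestinCre control was lower than Flox control for this list (median -0.11, 18 of 23 below 0), which did not pass there (limma camera adjusted p = 0.0529).

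**Figure D2:**
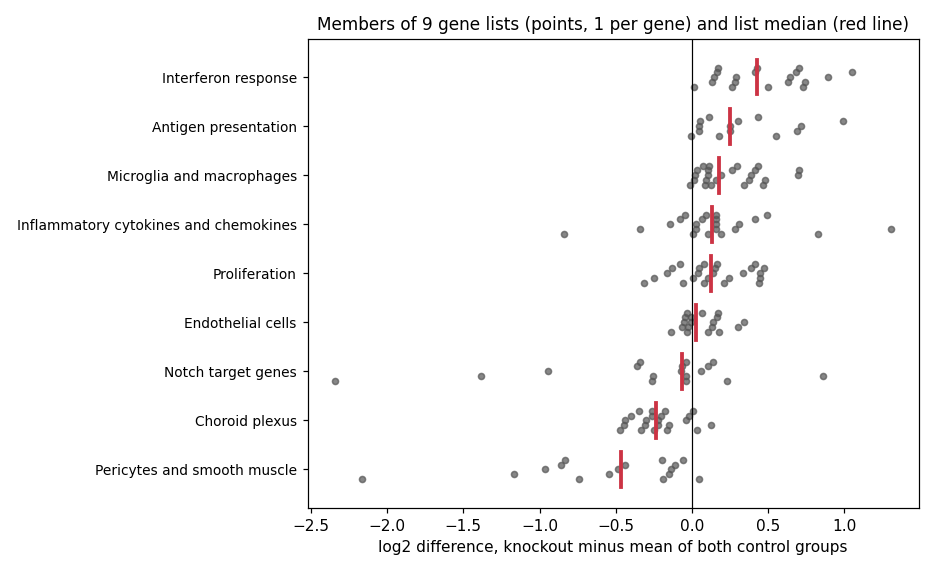
Log2 difference between knockout and the mean of both control groups (horizontal axis) for each measured member of 9 gene lists (points, 1 per gene, spread vertically for legibility only), with the list median in red. All 19 interferon-response points lie above 0 around a median of 0.43, and 15 of 16 pericyte and smooth muscle points lie below 0 around a median of -0.46.

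Choroid plexus genes were lower (median -0.24, 19 of 22 below 0), with Kcne2 (-0.47), Kl (-0.40), Kcnj13 (-0.45) and Clic6 (-0.44) first, and none passed over the list alone. Limma's camera gave an adjusted p of 1.24e-04, or 0.532 with an estimated correlation. Proliferation genes were higher (median 0.12, 18 of 24 above 0), with Mki67 (0.47), Top2a (0.45), Cdk1 (0.44) and Hmgb2 (0.44) first and none past the list-alone threshold (limma camera adjusted p = 1.99e-04, or 0.497 with an estimated correlation).

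The remaining 7 lists past the threshold each lost it when particular arrays were left out. Neural stem and progenitor genes were lower (median -0.15), and Thbs4 (-0.86), Rlbp1 (-0.85), Eomes (-0.24) and Sox21 (-0.43) fell over the list alone. The limma camera adjusted p was 0.0188, or 0.102 without NestinCre control replicate 2, 0.184 without knockout replicate 2 and 0.0588 with the female arrays alone. Astrocyte genes were lower (median -0.14), with Gpc5 (-0.51) and Slc1a2 (-0.23) falling over the list alone and Gfap and Aqp4 (0.25) rising. Their limma camera adjusted p was 0.0188, or 0.0803 without Flox control replicate 2 and 0.0515 without knockout replicate 2. Oligodendrocyte precursor genes were higher (median 0.12, adjusted p = 0.00587 by limma's camera, 0.137 without Flox control replicate 2). Of these Vcan rose over the list alone (0.72, SE 0.11), while Bcan (-0.42), Olig1 (0.27) and Gpr17 (0.61) did not pass. With an estimated correlation the adjusted p of these 3 lists was 0.565, 0.530 and 0.640.

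Glucocorticoid and stress genes had a median of 0.14 and a limma camera adjusted p of 0.00157, or 0.621 without knockout replicate 2. Immediate early genes had a median of -0.19 and an adjusted p of 0.0176, which became 0.203 without NestinCre control replicate 2, 0.0642 without Flox control replicate 1 and 0.620 without knockout replicate 2. For cholesterol synthesis the median was -0.13 and the adjusted p 0.0188, or 0.0803 without Flox control replicate 2, 0.598 without knockout replicate 1 and 0.494 with the female arrays alone. Against NestinCre control these genes did not pass (median 0.0056, 8 of 16 above 0, limma camera adjusted p = 0.958). Against Flox control they were lower (median -0.26, limma camera adjusted p = 5.25e-04, or 0.617 with an estimated correlation), and 9 of 16 fell over the list alone. Hippocampal neuron genes had a median of -0.10 and an adjusted p of 0.0438. It became 0.223 without NestinCre control replicate 2, 0.171 without Flox control replicate 2, 0.292 without knockout replicate 1 and 0.503 with the female arrays alone, and it was 0.0912 against NestinCre control and 0.0771 against Flox control. Against both controls, no member of these 4 lists passed over the list alone, and with an estimated correlation limma's camera gave each an adjusted p of 0.650 there.

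In all, 15 of 43 lists passed with the preset correlation, and none did with an estimated one. The female arrays alone hold 1 knockout array, so they cannot show whether these lists hold up. The astrocyte and oligodendrocyte precursor lists did not pass against Flox control alone (limma camera adjusted p = 0.0914 for each). The 28 others had limma camera adjusted p between 0.0753 and 0.927. Besides the Notch and endothelial lists they were neuroblasts, pan-neuronal, glutamatergic, GABAergic, and monoaminergic and cholinergic neurons, myelinating oligodendrocytes, meninges and fibroblasts, ependymal cells, striatal neurons, cerebellar cells, olfactory bulb, hypothalamus and thalamus, and pituitary. The rest were haemoglobin and erythroid genes, heat shock, apoptosis and p53, oxidative phosphorylation, glycolysis, ribosomal proteins, Wnt signalling, BMP, TGF-beta and hedgehog signalling, O-fucosylation substrates, neighbours of Pofut1 and sex-linked genes. Limma's fry, which asks whether members move one way without comparing them with other genes, passed 4 lists: interferon response, pericytes and smooth muscle, cytokines and chemokines, and glutamatergic neurons (median -0.09, fry adjusted p = 0.00860). Members of the 28 lists that passed over the list alone included Lum (-0.30), Aldh1a2 (-0.35), Sfrp1 (-0.43) and Rspo1 (-0.40), which fell, and Col6a1 (0.41) and Dcn (0.44), which rose.

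Against NestinCre control alone, which differs in the floxed copies of Pofut1, no probe set passed, and the genes named by the rule follow. Lower in knockout were 2900052N01Rik (log2 difference -2.15, SE 0.08), Rgs5 (-2.13, SE 0.09), 1 probe set of the splicing factor Rbm39 (-2.98, SE 0.15), Notch3 (-1.13, SE 0.06) and Nrarp (-2.21, SE 0.14). Higher were Paip1 (1.88, SE 0.09), Cxcl10 (1.33, SE 0.07), Fcgr4 (1.71, SE 0.09), Cp (0.75, SE 0.05) and H2-D1 (0.87, SE 0.06). The Rbm39 probe set averaged 9.29 on the log2 scale in NestinCre control, 6.10 in Flox control and 6.31 in knockout, and 6 of the gene's 12 probe sets differed in that direction. The smallest limma adjusted p was 0.0574, and 2617 probe sets had an unadjusted p under 0.05 against 2251.8 expected. Of the lists, 13 passed limma's camera and 0 did with an estimated correlation, where the smallest adjusted p was 0.135. Interferon-response (median 0.47) and pericyte and smooth muscle genes (median -0.45) were among the 9 that passed whichever array was left out.

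Against Flox control alone, which differs in Cre, Rgs5 (-2.19, SE 0.09) and 2900052N01Rik (-2.08, SE 0.08) fell, both with a limma adjusted p of 0.0495. Named without passing were Notch3 (-1.09), Nrarp (-2.47) and Papss2 (-1.70), which were lower, and Paip1 (1.78), Fcgr4 (1.79), Cxcl10 (1.28), AU020206 (0.88) and the imprinted non-coding RNA Meg3 (0.86), which were higher. All 11 Meg3 probe sets differed in that direction. There were 7179 probe sets at an unadjusted p under 0.05, and 0 adjusted calls when any 1 array was left out. Of the lists, 12 passed limma's camera and 0 with an estimated correlation (smallest adjusted p = 0.237), and 7 passed whichever array was left out. Both Flox control arrays were from females and carried high pituitary transcripts, with Gh at 7.87 and 9.40 and Prl at 7.28 and 9.58 on the log2 scale.

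No probe set passed in knockout against each control in the same direction. At an unadjusted p under 0.01 against each, 434 did, 246 higher and 188 lower. The comparisons share the knockout arrays, and in 20 simulations of unchanged groups the same count averaged 138.75 and reached 160 at most. The simulations drew each probe set independently, with the same mean in all groups, so they may understate how far such a count varies. Independent lists would share 11.9 higher and 6.81 lower probe sets. The covariance of the log2 differences was 0.0236, against 0.0122 in the simulations, and their correlation across probe sets was 0.553 against 0.499. Part of the excess over independent lists may come from the shared arrays, which the simulations also share.

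The controls were compared to see what Cre and the floxed copies carry with them. NestinCre control was higher than Flox control for a probe set of Rbm39 (log2 difference 3.18, SE 0.15), for Rprd1b (1.22, SE 0.09), Meg3 (0.66, SE 0.06), Gle1 (0.71, SE 0.06) and Shkbp1 (0.65, SE 0.06). It was lower for Ntn4, a laminin-related netrin (-1.25, SE 0.09), the thrombin receptor F2r (-1.21, SE 0.10), Ro60 (-2.13, SE 0.18), Gdpd3 (-3.09, SE 0.31) and Abi3bp (-0.56, SE 0.06). Each value is that of 1 probe set, and other probe sets of a gene did not always follow. Only 1 of 3 for Rprd1b and 1 of 4 for Ro60 had an unadjusted limma p under 0.05 in that direction. For Gle1, 4 of 7 differed in that direction. None passed: the smallest limma adjusted p was 0.216, with 4693 probe sets at an unadjusted p under 0.05. Cholesterol synthesis genes were lower in NestinCre control (median -0.24, 16 of 16 below 0, limma camera adjusted p = 2.12e-05, or 0.928 with an estimated correlation). Striatal neuron genes were lower as well (median -0.17, limma camera adjusted p = 0.0337, or 0.928 with an estimated correlation). The striatal value became 0.606 without NestinCre control replicate 1, 0.0911 without Flox control replicate 1 and 0.0736 without Flox control replicate 2. Of 10 pituitary genes, 4 were lower in NestinCre control over the list alone, among them the hormone genes Gh (-2.76, SE 0.50), Prl (-2.97, SE 0.74) and Pomc (-0.79, SE 0.21), and the list did not pass (limma camera adjusted p = 0.318).

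The Rbm39 and Rprd1b probe sets belong to genes on the chromosome of Pofut1. By a rule chosen after their values were seen, a probe set was counted when NestinCre control differed from the other 4 arrays by at least 0.6 on the log2 scale with a gap of at least 0.3. Of 335 probe sets of the 100 protein-coding genes on each side of Pofut1, 11 did so, from 8 genes that included Rbm39, Epb41l1 (-1.63), Mapre1 (0.91) and Cep250 (0.83). Of probe sets with 1 gene, another 31 of 34610 elsewhere did so, 8 of them on chromosome 7, with Gdpd3 (-3.28) and Tial1 (2.05) first. Near Pofut1, probe sets of the same gene did not all follow. Other Mapre1 probe sets differed by -0.29, 0.40, 0.09 and 0.01, and another of Epb41l1 by -0.05. The Cnbd2 probe sets that were counted went opposite ways, at -0.79 and 0.66.

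**Figure D3:**
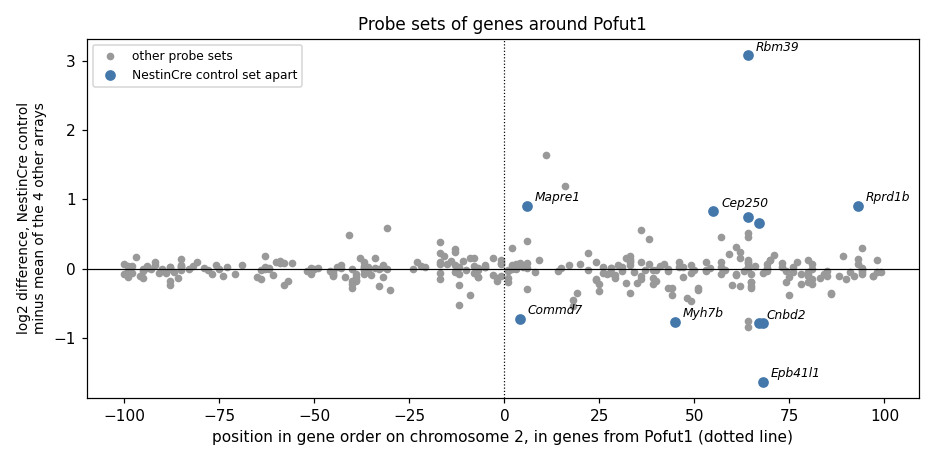
Log2 difference between NestinCre control and the mean of the 4 other arrays (vertical axis) for each of 335 probe sets of genes around Pofut1, placed by gene order on chromosome 2 (horizontal axis, in genes from Pofut1, dotted line). The 11 blue probe sets set NestinCre control apart by the rule above, and all lie from 4 to 93 genes to the right of Pofut1.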

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

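Sex as a covariate and the female arrays alone were added after seeing the data. The counts of calls moved with the variance model and with which probe sets were tested, whereas directions of named genes did not turn under any alternative. For knockout against both controls, 7 probe sets passed. There were 22 with each array centred on its median, 34 with probe sets above the median only, 76 above the lower quartile, 135 with an intensity trend, 202 with a robust trend, 28 with the controls as 1 group, and 34 with 1 probe set per gene. Against NestinCre control (0 calls) the counts were 9 after centring, 11 and 27 under the filters, 39 and 72 with the trends, 1 with only those groups, and 10 with 1 probe set per gene. Against Flox control (2 calls) they were 0 after repeated quantile normalization, 9 after centring, 23 and 81 under the filters, 162 and 325 with the trends, 0 with only those groups, 20 with 1 probe set per gene and 0 with log2 of the value plus 16. Between controls (0 calls) there were 1 above the lower quartile, 1 with the trend and 6 with the robust trend. Calls against each control in 1 direction (0) became 7 after centring, 9 and 20 under the filters, 29 and 54 with the trends, and 10 with 1 probe set per gene. With sex as a covariate or the female arrays alone, there were 0 calls against both controls and 0 against Flox control. Fewer probe sets tested and fewer arrays or degrees of freedom are part of those alternatives; beyond that the cause was not tested.

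The replicate number did not pair the samples: correlations of same-numbered deviations between groups were 0.189, -0.310 and -0.237. With it as a block, 0 probe sets passed against both controls and 0 against Flox control, while the list count between controls became 4. Leaving out 1 array gave 0 to 1 calls against both controls, 0 to 1 against NestinCre control, 0 to 0 against Flox control, 0 to 2 between controls and 0 to 0 against each control, and 0 of these had passed with all arrays. A lone array left in a group is then assumed to vary like the other groups. The log2 difference of Pofut1 stayed between -0.59 and -0.40. Lists past the threshold numbered 11 to 20 against both controls, 10 to 18 against NestinCre control, 8 to 15 against Flox control and 2 to 4 between controls.

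Against both controls 15 lists passed, 9 with genes above the median only, 0 with an estimated correlation and 4 with fry, of which 3 were among the 15. Against NestinCre control there were 0 and 3 under the last pair of settings, and against Flox control 0 and 4, of which 3 had passed. Between controls, 2 lists became 1 with the mean of all probe sets, 4 with genes above the median only, 5 with the female arrays alone, 0 with an estimated correlation and 0 with fry. The list of cytokines and chemokines turned direction with genes above the median only, with limma camera adjusted p of 0.377 against both controls, 0.834 against NestinCre control and 0.194 against Flox control. The lowest intensity was near 38.1 on each array, so differences of dim probe sets are compressed.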

Other observations

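The tests of explanations below were chosen after the results were seen, except the count over placements of the arrays. Values over genes treat members as exchangeable, and genes are not independent replicates.

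Striatal neuron genes had a median of 0.26 between the female knockout and female NestinCre control arrays and -0.09 between the males, and glucocorticoid and stress genes 0.37 and 0.12. Each pair is a single array against a single array, so these are values with no test.

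Genes of pericytes and smooth muscle were lower in knockout. A lower yield of vessels would lower endothelial genes alike, but their median lay 0.49 above that of the mural genes (95% bootstrap interval 0.16 to 0.88). Knockout and NestinCre control each held 1 male and 1 female array, so an additive effect of sex cancels between them, and there the median was -0.45 and 9 of 16 members fell by limma when adjusted over the list alone (fry adjusted p = 0.0155, and 0.157 by camera with an estimated correlation), which argues against sex as the whole source. Fewer mural cells with every marker lowered alike cannot be told apart from the rest, because differences of dim members are compressed and only 3 of 16 lay above the upper quartile of brightness, of which the intervals of 2, Rgs5 (-2.16) and Vtn (-0.19), left out their median of -0.84. A change of expression within mural cells, a partial loss with some markers shared by other cells, and the knockout as its origin stay open and were not tested.

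Interferon and antigen presentation genes were higher in knockout. Between knockout and NestinCre control, balanced for sex, 12 of 19 interferon genes (median 0.47, limma's fry adjusted p = 0.0155, and 0.135 by camera with an estimated correlation) and 6 of 14 antigen presentation genes (median 0.27, fry adjusted p = 0.0822, and 0.321 by camera with an estimated correlation) rose by limma when adjusted over the list alone, which argues against an additive effect of sex of the animals as the whole source. Antigen presentation genes were also lower in NestinCre control than in Flox control (median -0.24). Against Flox control their knockout median was 0.17 (limma's fry adjusted p = 0.160). More blood would raise haemoglobin, but Hba-a2, the brightest haemoglobin gene, differed by -0.0031 (95% interval -0.15 to 0.14), below the interferon median of 0.43. More microglia alone cannot be told apart from the rest, since the interferon median lay 0.27 above that of the 23 microglial genes on neither list (0.16, or 0.17 with all 24), with a 95% bootstrap interval from -0.01 to 0.54. A response to the knockout and a shared litter, cage or infection of the knockout animals remain open, untested.

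Some probe sets of genes near Pofut1 set NestinCre control apart from both groups with floxed copies, by at least 0.6 on the log2 scale with a gap of at least 0.3, a rule set after these values were seen, so its counts only describe them. A change of the whole Rbm39 transcript level is argued against by its 12 probe sets, of which 2 stood apart in that direction and the brightest differed by 0.03. A haplotype inherited with the floxed allele may account for the probe sets near Pofut1, as a hypothesis that would have NestinCre control differ from both other groups, and them not from each other. The 42 measured neighbours of Pofut1 on a list fixed before the data were examined did not decide it: limma's fry for change in either direction gave an adjusted p of 0.213 between knockout and NestinCre control, 0.0262 between the controls and 0.0240 between knockout and Flox control, and no sequence was examined. Of the genes set apart, that list held only Commd7 and Mapre1, and not Rbm39, Epb41l1, Cep250, Cnbd2, Myh7b or Rprd1b. The test used the brightest probe set of each gene, so it covered little of the pattern. The haplotype hypothesis leaves aside the 31 probe sets elsewhere, of which 8 lay on chromosome 7 (Gdpd3 at -3.28, Tial1 at 2.05, Trim34a at 1.16) and others on chromosomes 1 and 10 (Ro60 at -2.04, Mir1931 at 1.42). The same rule set Flox control apart for 3 of 335 probe sets near Pofut1 and 124 of 34610 elsewhere. It set knockout apart for 0 of 335 and 178 of 34610, and NestinCre control for 11 of 335 and 31 of 34610.

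The arrays were placed 2 against the other 4 in each of the 15 ways, in a limma fit with the 4 others as 1 group, where knockout against the controls has 28 calls and not the 7 found with a mean for each control group. In that fit 1 placement, the real one, reached 28, and the highest of the others had 22. The 15 placements are too few for a share under 0.05. The placement with 22 calls set the 2 male arrays against the rest, and all 11 of its probe sets with 1 gene were on X or Y.

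Among hybridisation spikes, the bio probe sets averaged 12.05 on NestinCre control replicate 1 on the log2 scale and 11.14 to 11.47 on the other arrays, and the cre probe sets 13.97 and 13.79 to 13.85. The first principal component held 45.4% of the variance and ran from -35.7 on Flox control replicate 1 to 36.5 on knockout replicate 1. It did not separate knockout from the controls. Knockout replicate 2 lay at 3.55, between NestinCre control replicate 1 (-1.25) and replicate 2 (17.3). Of the 64 control probe sets, 0 passed between knockout and both controls by limma, with a smallest adjusted p of 0.980.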
